A study of Mus musculus with 6 samples.

How the data were processed

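RNA from mouse cells labelled as lymphatic endothelial cells of the heart was sequenced in 6 libraries, 3 sham and 3 MI, all at day 3. Groups and replicate numbers were taken from the sample titles. The protocol text in the labels speaks of heart tissue or primary cardiac endothelial cells without saying which was used here, names serum-containing culture medium, and gives no sorting or purification step.

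The deposited table gave estimated counts per gene and library, made by the authors from reads mapped to the mouse genome GRCm38 and not scaled, with 2 decimals. The same table gave FPKM and TPM computed by the authors, and a scaled read count (a signal value) in which the authors divided the counts of each library by a nearly constant factor, with a median of 0.434 to 0.485 in sham and 2.16 to 2.19 in MI. The genome build GRCm38.p6 is named in the submitters' processing notes. The aligner, the counting program, the annotation release and any filter were not given in the sources used here. The submitters' processing notes also name Agilent Feature Extraction 9.1, a microarray program, with no role. Group averages in the table were the authors' own and were not used here. The table listed 17714 genes by symbol and Entrez identifier, of which 62 had 0 counts in every library and 17576 matched a RefSeq table of GRCm38.p6 that supplied positions and gene types. Counts can be divided among near-identical genes, and no strand setting was given, so overlapping genes and paralogs are uncertain.

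Estimated counts were rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 removed low-count genes with filterByExpr (13370 kept), scaled libraries by TMM, and fitted the quasi-likelihood model with the group as the only term. Genes were called at a two-sided Benjamini-Hochberg adjusted p below 0.05 over all genes tested. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries. Log2 fold changes are MI minus sham, and their SE is the log2 fold change divided by the square root of the quasi-likelihood F. The fold of a gene with 0 counts in a group was computed against 3 counts over that group and is a lower bound for counting error only. The sham libraries, with 3206732 to 3591473 counts, set the lower limit of detection. The common biological coefficient of variation was 0.103, from 0.0426 within sham and 0.121 within MI. Ratios between a gene and a list used the mean log2(CPM + 0.5) of the list and an exact two-sided permutation test, whose smallest possible p is 0.1; 8 such measures were tested, with no adjustment.

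Before the data were examined, 30 gene lists (18 programs and 12 cell-type or handling sets) and the rule for named genes were fixed. The rule took Ccl2, then the 8 largest rises and 8 largest falls among genes with an official symbol that passed the threshold, whose groups did not overlap and whose mean reached 5 CPM in the higher group, and up to 4 members with the smallest p from each list described. Genes named outside the rule are marked as such, apart from those given here. Ctsb, Psap, Apoe, Ftl1, Eef1a1, Plvap, Cd163, Il33, Ptprc, Lyz2, LOC118568718 and Gm20594 were named because of their abundance or their place in a count. Icam2 and Mrc1 were named for shared list membership, and Ccr9 and Ngp as members set at a bound. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over 28 lists. The preset-correlation test compares a list with all other genes; fry called 26 lists in one direction and 28 in either direction, which compares no list with other genes.

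Alternatives fixed in advance were DESeq2 1.42.0, RLE scaling, no filter, a stricter filter (1 CPM in all libraries of a group and a total of 100 counts), the replicate number as a block, each library left out in turn, a minimum fold change of 2, and limma-voom. Added after seeing the data were MI libraries thinned at random to the sham depth, scaling to total counts, leaving out LOC118568718 and Gm20594 (0.858% of sham counts and 0.00734% of MI counts for the latter), and limma with trend on log2(TPM + 1) for genes with a TPM of at least 1 in 3 libraries. For the list tests, RLE scaling and the stricter filter were also added after seeing the data. Further gene lists written after the main results were seen appear in the closing section.

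The procedure was tested on simulated data for the comparison of sham with MI. Each of 13370 genes had its mean over all 6 libraries, the real depths and 1 dispersion shared by both groups. Of these genes, 200 were changed, and 74% of the 2-fold and 38% of the 1.5-fold changes were recovered. Of 119 calls, 7 (5.88%) were unchanged genes, and 7 of 200 random lists had a camera p below 0.05. The simulated changes were few and balanced between rises and falls, whereas 73.3% of tested genes were called in the real comparison. Recovery and scaling under so broad a change were therefore not tested. Genes were drawn independently. False calls under unequal spread in the groups, and camera with correlated genes, were therefore not tested either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.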

Results

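RNA sequencing libraries of mouse cells labelled as cardiac lymphatic endothelial cells were compared between myocardial infarction (MI) and sham operation, both labelled day 3, with 3 libraries in each group. All 6 libraries were labelled wild type. Lymphatic endothelial cells line the vessels that drain fluid and immune cells from a tissue, and the series title names the chemokine CCL2, lymphatic growth and macrophage clearance as its subject. The sham libraries held 3206732 to 3591473 estimated counts (mean 3415315 ± 194409, SD, n = 3), and the MI libraries held 21154342 to 21689333 (mean 21465763 ± 278105, SD, n = 3), 6.29 times as many. Genes with at least 1 count numbered 14631 ± 48.4 in sham and 16355 ± 47.2 in MI. Depth thus followed the group; with the MI libraries thinned to the sham depth, an alternative added after seeing the data, 8624 genes passed, 8393 of them shared with the main analysis. An unstated library batch that followed the group cannot be told apart from the operation. The labels do not say that libraries came from separate animals, and the p-values measure only the spread between these libraries.

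The libraries separated by group. Across tested genes, Pearson's r of log2 CPM (counts scaled to library size) was 0.974 to 0.976 between sham libraries, 0.988 to 0.995 between MI libraries and 0.789 to 0.794 between groups; these are correlations across genes, which are not independent replicates. The first principal component held 90.04% of the variance and placed the 3 sham libraries on one side and the 3 MI libraries on the other. Pairs of one group differed beyond counting noise, by a chi-square per gene of 1.55 to 1.79 between sham libraries and 4.47 to 37.4 between MI libraries, where MI 1 stood farthest from the others, so none was counted as a repeat deposit. The sham excess was small (biological coefficient of variation 0.0426 within sham, 0.121 within MI). It does not tell separate animals from repeated libraries of the same material, and the p-values rest on this spread. The most abundant named transcripts in every sham library included Eef1a1, a translation factor, the lipid carrier gene Fabp4 and the fatty acid receptor gene Cd36. In every MI library they included the lysosomal protease gene Ctsb, the lysosomal activator gene Psap, the lipoprotein gene Apoe and the ferritin gene Ftl1. The unnamed gene LOC118568718 took 3.65 ± 0.292% of the sham counts and 0.0308 ± 0.00326% of the MI counts (SD, n = 3).

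Between sham and MI, transcripts of macrophages, neutrophils, NF-kB targets and the cell cycle were higher in MI, while transcripts of endothelial cells, cardiomyocytes, red blood cells and mural cells were lower. Markers of several cell types were present in both groups, so no fold change below is specific to lymphatic endothelial cells. Cd68, a lysosomal protein of macrophages, went from 99.95 ± 4.10 to 1448 ± 174 CPM (mean ± SD, n = 3), and Pecam1, a junction protein of endothelial cells, went from 1604 ± 19.6 to 386 ± 5.90 CPM. Of 13370 genes tested, 9801 (73.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4861 of them higher and 4940 lower in MI. A change of at least 2-fold was estimated for 2705 of the higher and 2829 of the lower genes. The groups did not overlap at 10173 genes (76.1%), against 10% by chance with 3 libraries on each side. When a fold change above 2 was itself tested, 4160 genes passed. Scaled to total counts, an alternative added after seeing the data, 3549 genes were higher and 6628 lower, so higher calls made up 34.9% instead of 49.6%, and the median log2 fold change over all genes was -0.36 instead of -0.01.

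The rule for named genes took 8 rises by fitted fold change, all in genes with 0 counts in all 3 sham libraries. Their folds are lower bounds against 3 counts over the sham group (0.26 CPM), which do not rank them against genes counted in both groups. Tarm1, an activating receptor of myeloid cells, reached 22.1 ± 1.67 CPM in MI and was at least 85.3-fold higher. The others were Stra6l, at least 77.2-fold higher, Evi2, at least 50.7-fold, Tnfsf4, which encodes the costimulatory ligand OX40L, at least 29.8-fold, Spint1, a protease inhibitor, at least 28.4-fold, Mrgpra2a, at least 27.3-fold, the neuropeptide gene Npy, at least 26.6-fold, and Aqp9, a water and glycerol channel, at least 26.4-fold. Among the falls, Bpifa1, an airway secretory protein, had 0 counts in MI and was at least 258-fold lower. Retnla, a marker of alternatively activated macrophages, went from 54.6 ± 3.97 to 0.404 ± 0.202 CPM and fell 132-fold (log2 fold change -7.04 ± 0.21, SE). Scgb1a1, a secretory protein of airway club cells with 4 counts over the MI libraries, fell 89.6-fold. Its log2 fold change ran from -7.67 to -4.72 over the alternatives. Ahsg, a liver plasma protein, fell 66.5-fold, and Cd207, a lectin of Langerhans and some dendritic cells, 41.3-fold. The atrial myosin light chain gene Myl7 fell 39.9-fold, Lrtm1 32.2-fold and the muscle mitochondrial creatine kinase gene Ckmt2 31.8-fold. Mrgpra2a has near-identical relatives among which reads could be divided, so its value is uncertain.

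**Figure D1:**
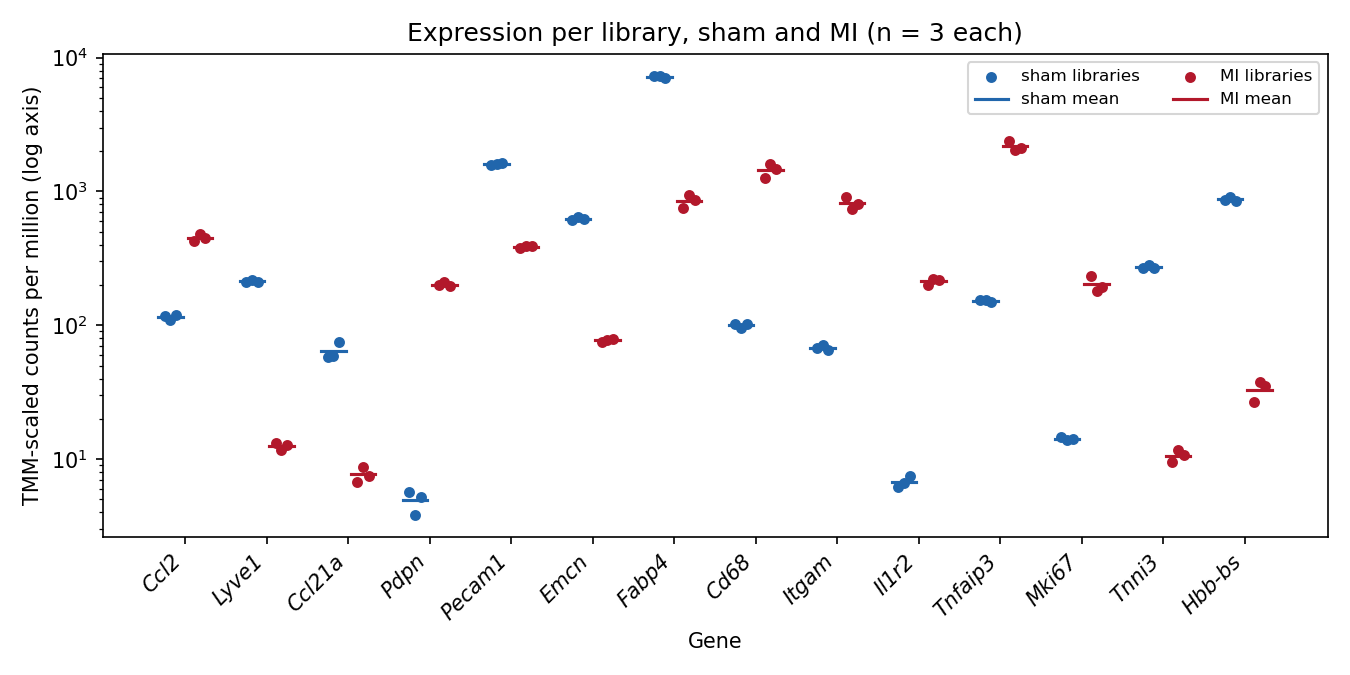
TMM-scaled CPM on a log axis for 14 genes in each of the 3 sham (blue) and 3 MI (red) libraries, with a line at each group mean. For every gene shown the 3 MI libraries lie on one side of the 3 sham libraries, with Ccl2 at a mean of 116 CPM in sham and 451 CPM in MI.

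Ccl2, which encodes the monocyte-attracting chemokine named in the series title, was 3.89-fold higher in MI, going from 116 ± 5.83 to 451 ± 26.0 CPM (SD, n = 3). Its log2 fold change was 1.96 ± 0.08 (SE), with an adjusted p of 1.13e-09 in edgeR's quasi-likelihood test, and all 3 MI libraries (428 to 479 CPM) lay above all 3 sham libraries (109 to 120.1 CPM). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries can give. The gene (Entrez 20296) lies on chromosome 11 from 82035577 to 82037452 of GRCm38.p6 and is annotated as protein coding. Relative to the mean log2 CPM of the macrophage and monocyte list, Ccl2 was 0.74 log2 units lower in MI than in sham (0.35 ± 0.10 in sham, -0.40 ± 0.03 in MI). Set against the pan-endothelial list it was 4.14 higher (-1.85 ± 0.06 in sham, 2.29 ± 0.04 in MI). Both differences exceeded the spread between replicates, and each had p = 0.1 in the exact two-sided permutation test. The cells within a library that carried the Ccl2 transcripts are not resolved by these data.

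Most chemokines with a change rose, among them attractants of neutrophils and of monocytes. Of 29 chemokine genes tested, 19 rose and 7 fell, or 19 and 8 adjusted over the list alone (median log2 fold change 1.91). Cxcl3 rose 87.2-fold, from 5.01 ± 2.11 to 432 ± 18.2 CPM, and Cxcl2, also a neutrophil attractant, rose 12.8-fold, from 595 ± 53.2 to 7589 ± 947 CPM. Ccl3 rose 7.44-fold and Ccl7, a ligand of the Ccl2 receptor, 5.64-fold. Among the members that fell, Cxcl12, named after its value was seen, fell 3.96-fold and Ccl21a 8.29-fold. Of 15 chemokine receptor genes tested, 12 rose and 3 fell, the same adjusted over the list alone, with a median of 2.996, or 2.92 with Ccr9 (0 counts in sham) at its bound. Ccr2, the receptor of Ccl2 on monocytes, rose 27.0-fold, from 4.80 ± 1.63 to 131 ± 27.9 CPM, Ccrl2 15.6-fold and Ccr1 7.98-fold, and the scavenging receptor gene Ackr3 fell 4.74-fold. Both lists ranked above other genes in limma's camera test (adjusted p = 2.15e-05 for chemokines, 1.76e-04 for receptors), a call lost when the correlation between genes was estimated (adjusted p = 0.118 and 0.122). In the same libraries the macrophage list had a median of 2.79 and the pan-endothelial list one of -2.12.

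Leukocyte adhesion and transmigration genes went both ways, with 8 higher and 11 lower of 20 tested (median -0.78), the same adjusted over the list alone. Cd44, a hyaluronan receptor, rose 17.4-fold, from 83.4 ± 9.69 to 1449 ± 199 CPM, while the junction gene Jam2 fell 7.70-fold and Pecam1 4.15-fold. Vcam1, named after its value was seen, was at 86.2 ± 8.91 CPM in sham and 95.0 ± 10.6 CPM in MI and did not pass. The list as a whole did not pass camera (adjusted p = 0.0619); it passed without sham 1 (adjusted p = 0.0478), without sham 3 (0.0464) or with libraries scaled to total counts (0.0404), against an adjusted p of 0.152 with an estimated correlation. Pecam1 and Icam2 are also in the pan-endothelial list (median -2.12), Lyve1 in the lymphatic list (-1.52) and Mrc1 in the macrophage list (2.79).

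Endothelial transcripts were lower in MI. All 19 pan-endothelial genes tested fell (median -2.12; 19 adjusted over the list alone), among them Emcn, a surface sialomucin, which fell 8.11-fold from 626 ± 16.7 to 77.1 ± 1.99 CPM, the angiopoietin receptor gene Tek (5.58-fold) and the endothelial transcription factor gene Erg (4.57-fold). Of 20 blood endothelial genes tested, 19 fell and 1 rose (median -2.002), the same adjusted over the list alone. Fabp4 went from 7169 ± 158 to 855 ± 96.6 CPM, Tcf15 fell 15.2-fold, Car4, a capillary carbonic anhydrase, 11.8-fold and Ly6c1 8.98-fold; Ly6c1 has a close paralog in Ly6c2, which makes its value uncertain. The gene that rose was Plvap (1.45-fold), which encodes a protein of endothelial diaphragms; its rise was not called with libraries scaled to total counts. Camera placed both lists below other genes (adjusted p = 6.67e-21 and 2.95e-15), also with an estimated correlation (adjusted p = 0.0223 for each). The macrophage list, with a median of 2.79, moved the other way in these libraries.

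Lymphatic endothelial markers mostly fell too, with 14 lower and 4 higher of 19 tested (median -1.52), the same adjusted over the list alone, although 2 instead of 4 were higher with libraries scaled to total counts. Lyve1, the lymphatic hyaluronan receptor that some tissue macrophages also carry, fell 17.1-fold, from 214 ± 3.89 to 12.5 ± 0.752 CPM. Ccl21a, the chemokine that guides dendritic cells into lymphatics, fell 8.29-fold, and Fxyd6, an ion pump regulator, 5.85-fold; Ccl21a has near-identical copies and its count is uncertain. Pdpn, which encodes podoplanin, a lymphatic surface protein also made by other cells, rose 40.8-fold, from 4.93 ± 0.96 to 202 ± 7.01 CPM. Prox1, the master regulator of lymphatic identity, named after its value was seen, fell 5.58-fold and stood at 7.12 ± 0.548 CPM in sham and 1.26 ± 0.456 CPM in MI. Per 100 Pecam1 CPM there were 0.444 ± 0.0296 Prox1 CPM in sham and 0.329 ± 0.124 in MI (SD, n = 3). Prox1 relative to the pan-endothelial list differed by 0.04 log2 units, within the replicate spread (exact permutation p = 0.8, n = 3 per group). The 0.04 depends on the 0.5 CPM added to each value, which raises the low MI value of Prox1 most. The ratio to Pecam1, without that addition, was lower in MI by less than the MI SD, so the direction is not settled. Lyve1 per 100 Pecam1 CPM was 13.3 ± 0.244 in sham and 3.24 ± 0.236 in MI, Flt4, the VEGF-C receptor gene, was 4.33 ± 0.303 and 7.66 ± 0.375, and Fabp4 was 447 ± 14.7 and 221 ± 21.9. The mean of the lymphatic list relative to that of the pan-endothelial list was 1.12 log2 units higher in MI (-4.56 ± 0.02 in sham, -3.44 ± 0.13 in MI, exact permutation p = 0.1, n = 3 per group). The 1.12 also depends on the added 0.5 CPM, and the mean fitted log2 fold changes were -1.30 (lymphatic) and -2.19 (pan-endothelial). Members of the lymphatic list did not move alike. Pdpn and Maf, both also made by other cells, had log2 fold changes of 5.35 ± 0.13 and 1.43 ± 0.14 (SE). Lyve1, Mmrn1 and Ccl21a, at -4.10 ± 0.10, -3.33 ± 0.20 and -3.05 ± 0.14, lay below the pan-endothelial median of -2.12. Maf and Mmrn1 were named after their values were seen. The lymphatic list passed camera (adjusted p = 0.00685) but not with an estimated correlation (adjusted p = 0.122).

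Of 30 genes for ligands and receptors of lymphatic growth, 21 fell and 9 rose (median -1.32), the same adjusted over the list alone. The fallen members included Tek and Tie1 of the angiopoietin system (5.58-fold and 4.11-fold), the apelin receptor gene Aplnr (4.79-fold) and the VEGF receptor gene Kdr (4.28-fold), of which Tek, Tie1 and Kdr are also in the pan-endothelial list and Aplnr in the blood endothelial list. Those lists had medians of -2.12 and -2.002. Named after their values were seen, the VEGF-C gene Vegfc fell 5.30-fold, its receptor gene Flt4 2.35-fold, and Vegfa rose 3.30-fold. With libraries scaled to total counts 6 rose instead of 9. Camera gave an adjusted p of 3.63e-05, and one of 0.0841 with an estimated correlation, which lost the call.

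Inflammatory genes rose nearly throughout the list of NF-kB targets and acute inflammatory genes, where 26 of 27 tested rose and none fell (median 2.53; 26 adjusted over the list alone). Tnfaip3, a feedback inhibitor of NF-kB, rose 14.2-fold, from 153 ± 2.88 to 2168 ± 177 CPM, Tnfaip2 18.9-fold, the cytokine gene Il1b 8.59-fold and Tnip1 9.85-fold. Il33, the member that did not pass, was at 7.34 ± 0.808 CPM in sham and 6.84 ± 2.03 CPM in MI. The camera call (adjusted p = 2.23e-20) held with an estimated correlation (adjusted p = 0.0124). Interferon-response genes were mixed, with 16 higher and 8 lower of 28 tested (median 0.49), the same adjusted over the list alone: Oas3 rose 72.1-fold, Oasl1 19.1-fold and the nucleic acid sensor gene Zbp1 11.1-fold, while Irf1, Gbp2 and Stat2, named after their values were seen, fell 3.06-fold, 1.75-fold and 1.23-fold. That list passed camera (adjusted p = 0.0188) and lost the call with an estimated correlation (adjusted p = 0.129). Its median ran from 0.14 to 0.55 over the alternatives. Antigen presentation genes showed 14 rises and 0 falls among 20 tested, the same adjusted over the list alone (median 0.43), with the checkpoint ligand gene Cd274 5.14-fold higher, Nlrc5 3.89-fold and the peptide transporter gene Tap1 1.89-fold. With libraries scaled to total counts 7 of them rose and 4 fell, and camera did not call the list (adjusted p = 0.0556) except without MI 1 (adjusted p = 0.0145) or without a filter on low counts (0.00299), against 0.55 with an estimated correlation. These lists moved in libraries where the macrophage list had a median of 2.79.

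Markers of myeloid cells were higher in MI. Of 22 macrophage and monocyte genes tested, 21 rose and 1 fell (median 2.79), the same adjusted over the list alone. Fcgr1, a high-affinity antibody receptor, rose 15.2-fold, Cd68 14.5-fold, the integrin gene Itgam 12.0-fold and Laptm5 10.1-fold. The member that fell was Cd163, a haemoglobin scavenger receptor of resident macrophages, named after its value was seen (7.47-fold, from 213 ± 5.62 to 28.5 ± 4.51 CPM). Per 100 Pecam1 CPM, the pan-leukocyte gene Ptprc stood at 6.61 ± 0.256 in sham and 178 ± 31.7 in MI, and the myeloid lysozyme gene Lyz2 at 119 ± 4.51 and 2333 ± 117 (SD, n = 3). Of 11 neutrophil genes tested, 9 rose and none fell, or 10 adjusted over the list alone (median 3.92, or 3.47 with Ngp, at 0 counts in sham, at its bound). Il1r2, a decoy interleukin-1 receptor, rose 31.6-fold, from 6.77 ± 0.64 to 214 ± 10.6 CPM, the granulocyte receptor gene Csf3r 15.2-fold and the calgranulin gene S100a9 22.3-fold. Camera called both lists (adjusted p = 1.53e-20 and 1.95e-07), also with an estimated correlation (adjusted p = 0.0223 and 0.0405).

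Lymphocyte genes did not pass as a list, with 2 higher, 2 lower and 4 not past the test of 8 (camera adjusted p = 0.856; the same counts adjusted over the list alone). Cd4, which some myeloid cells also carry, rose 5.36-fold, and the B cell gene Cd79a fell 5.91-fold. Cd79b rose 2.07-fold, a call that ended without sham 2 (adjusted p = 0.075 in edgeR's quasi-likelihood test) and with libraries scaled to total counts. Of 5 platelet genes tested, the chemokine genes Pf4 and Ppbp, both also in the chemokine list, rose 3.34-fold and 4.37-fold, and 3 did not pass; Itga2b and Gp1ba had log2 fold changes of 0.08 ± 0.31 and 0.04 ± 0.43 (SE), whose signs turned without sham 2 and with libraries scaled to total counts.

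Markers of the other cell types of the heart were mostly lower. Of 18 cardiomyocyte genes tested, 17 fell and none rose (median -4.19), the same adjusted over the list alone: Pln, a calcium pump regulator, went from 530.3 ± 21.8 to 24.3 ± 1.61 CPM, cardiac troponin I (Tnni3) fell 25.6-fold, Actc1 19.3-fold and Tnnt2 14.9-fold. All 5 erythroid genes tested fell (median -4.49; 5 adjusted over the list alone), with the beta-globin gene Hbb-bs 26.4-fold lower; the globin genes are near-identical pairs, which makes each single value uncertain. All 13 pericyte and smooth muscle genes fell (median -1.70; 13 adjusted over the list alone), among them Rgs5 (4.94-fold), Des (4.42-fold), Kcnj8 (6.42-fold) and Myh11 (2.76-fold). Camera called these 3 lists (adjusted p = 3.74e-30, 2.63e-09 and 1.05e-07), also with an estimated correlation (adjusted p = 0.0223, 0.0405 and 0.0223). Fibroblast genes parted, with 12 lower and 5 higher of 17 (median -1.42), the same adjusted over the list alone: the proteoglycan gene Dcn fell 5.65-fold, while the collagen genes Col1a1, Col3a1 and Col1a2 rose 6.30-fold, 3.10-fold and 3.15-fold. That list passed camera (adjusted p = 0.0183) and lost the call with an estimated correlation (adjusted p = 0.122). Of 5 mesothelial and epithelial genes tested, 4 fell, including Wt1 (2.88-fold), Tbx18 (2.89-fold) and Upk3b (5.28-fold), and 1 rose, Cdh1 (1 count in all sham libraries together), the same adjusted over the list alone (camera adjusted p = 0.324). Among Schwann cell and neuronal genes Tubb3 passed and was higher in MI, also adjusted over the list alone, on 6 counts over the sham libraries, and its log2 fold change ran from 1.22 to 3.28 over the alternatives. Fabp4 was the adipocyte gene tested and fell, also adjusted over the list alone; neither of these lists had the 5 tested genes needed for a list test.

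Cell cycle genes rose together, 38 of 40 tested with none lower (median 2.30; 38 adjusted over the list alone). The proliferation marker gene Mki67 went from 14.2 ± 0.376 to 202 ± 27.8 CPM, and Top2a, Tpx2 and Ube2c, which act in mitosis, rose 10.7-fold, 6.99-fold and 10.1-fold. Camera called the list (adjusted p = 3.33e-10), also with an estimated correlation (adjusted p = 0.0223). Genes of the unfolded protein response followed with 16 higher and 1 lower of 23 (median 1.001), the same adjusted over the list alone, including the chaperone gene Hspa5 (2.85-fold), Hyou1 (5.31-fold), Sdf2l1 (8.97-fold) and Calr (2.78-fold). Its camera call (adjusted p = 4.68e-04) held with an estimated correlation (adjusted p = 0.0428), and the lower member was Ddit3, a stress transcription factor gene named after its value was seen. With libraries scaled to total counts 6 instead of 1 of these genes fell. The macrophage list had its median of 2.79 in these libraries as well.

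Glycolysis and hypoxia genes were mostly higher, with 20 rises and 4 falls among 25 tested (median 0.96), the same adjusted over the list alone: hexokinase Hk2 rose 7.69-fold, the glycolytic genes Pkm and Pgam1 6.16-fold each, and the heme-degrading oxygenase gene Hmox1 7.62-fold. Camera called the list (adjusted p = 2.93e-06), though not with an estimated correlation (adjusted p = 0.193). Fatty acid handling genes were mostly lower, 17 of 27 against 5 higher (median -0.57), the same adjusted over the list alone: Fabp3 fell 12.3-fold, Gpihbp1, which holds lipoprotein lipase on capillaries, 7.47-fold and Cd36 4.46-fold, while the transporter gene Slc27a1 rose 16.9-fold. This call of camera (adjusted p = 0.0212) was also lost (adjusted p = 0.118 with an estimated correlation). In these libraries the cardiomyocyte list had a median of -4.19, the blood endothelial list, which also holds Cd36, one of -2.002, and the macrophage list one of 2.79. Oxidative phosphorylation genes fell at 19 of 32 and rose at 1, or 17 and 1 adjusted over the list alone (median -0.38), with Ndufa5 2.58-fold and Uqcrc2 1.62-fold lower; with libraries scaled to total counts 29 fell, and without MI 1 5 rose instead of 1. That list missed the threshold of camera (adjusted p = 0.0507) and passed it under several alternatives, among them without MI 2 (adjusted p = 0.018), without MI 3 (0.0472) and without sham 3 (0.0482), but with an estimated correlation the adjusted p was 0.677. Of 19 cholesterol synthesis genes, 10 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.345), with Mvd, an enzyme of the mevalonate pathway, 4.86-fold higher and Srebf2 1.94-fold; with libraries scaled to total counts 6 rose and 6 fell.

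Extracellular matrix genes parted, with 17 higher and 18 lower of 40 (camera adjusted p = 0.324), the same adjusted over the list alone; the median was 0.15 and turned to -0.20 with libraries scaled to total counts and to -0.01 in TPM. The matrix protein genes Thbs1 and Fn1 rose 48.2-fold and 7.56-fold, the protease gene Mmp14 rose 11.1-fold and Dcn fell 5.65-fold. Genes of endothelial-to-mesenchymal transition and TGF-beta signalling were higher at 10 and lower at 10 of 24 (camera adjusted p = 0.763), the same adjusted over the list alone, and higher at 7 and lower at 13 with libraries scaled to total counts (median -0.40 instead of -0.05): Vim rose 3.79-fold, and the BMP targets Id1 and Id3 fell 6.83-fold and 5.45-fold. Immediate-early genes, which tissue dissociation is known to induce, fell at 14 and rose at 6 of 23 (median -0.40), the same adjusted over the list alone. Fos fell 2.31-fold, Btg2 3.41-fold and Klf2, also a flow-induced endothelial gene, 3.12-fold, while Fosl1 rose 26.3-fold; 3 instead of 6 rose with libraries scaled to total counts. Camera called this list (adjusted p = 0.0409), a call lost with an estimated correlation (adjusted p = 0.439), without sham 3 (0.0512), without MI 3 (0.0666), with the replicate block (0.0548) and with RLE scaling (0.0513). In these libraries the pan-endothelial list had a median of -2.12, the macrophage list one of 2.79 and the cardiomyocyte list one of -4.19.

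**Figure D2:**
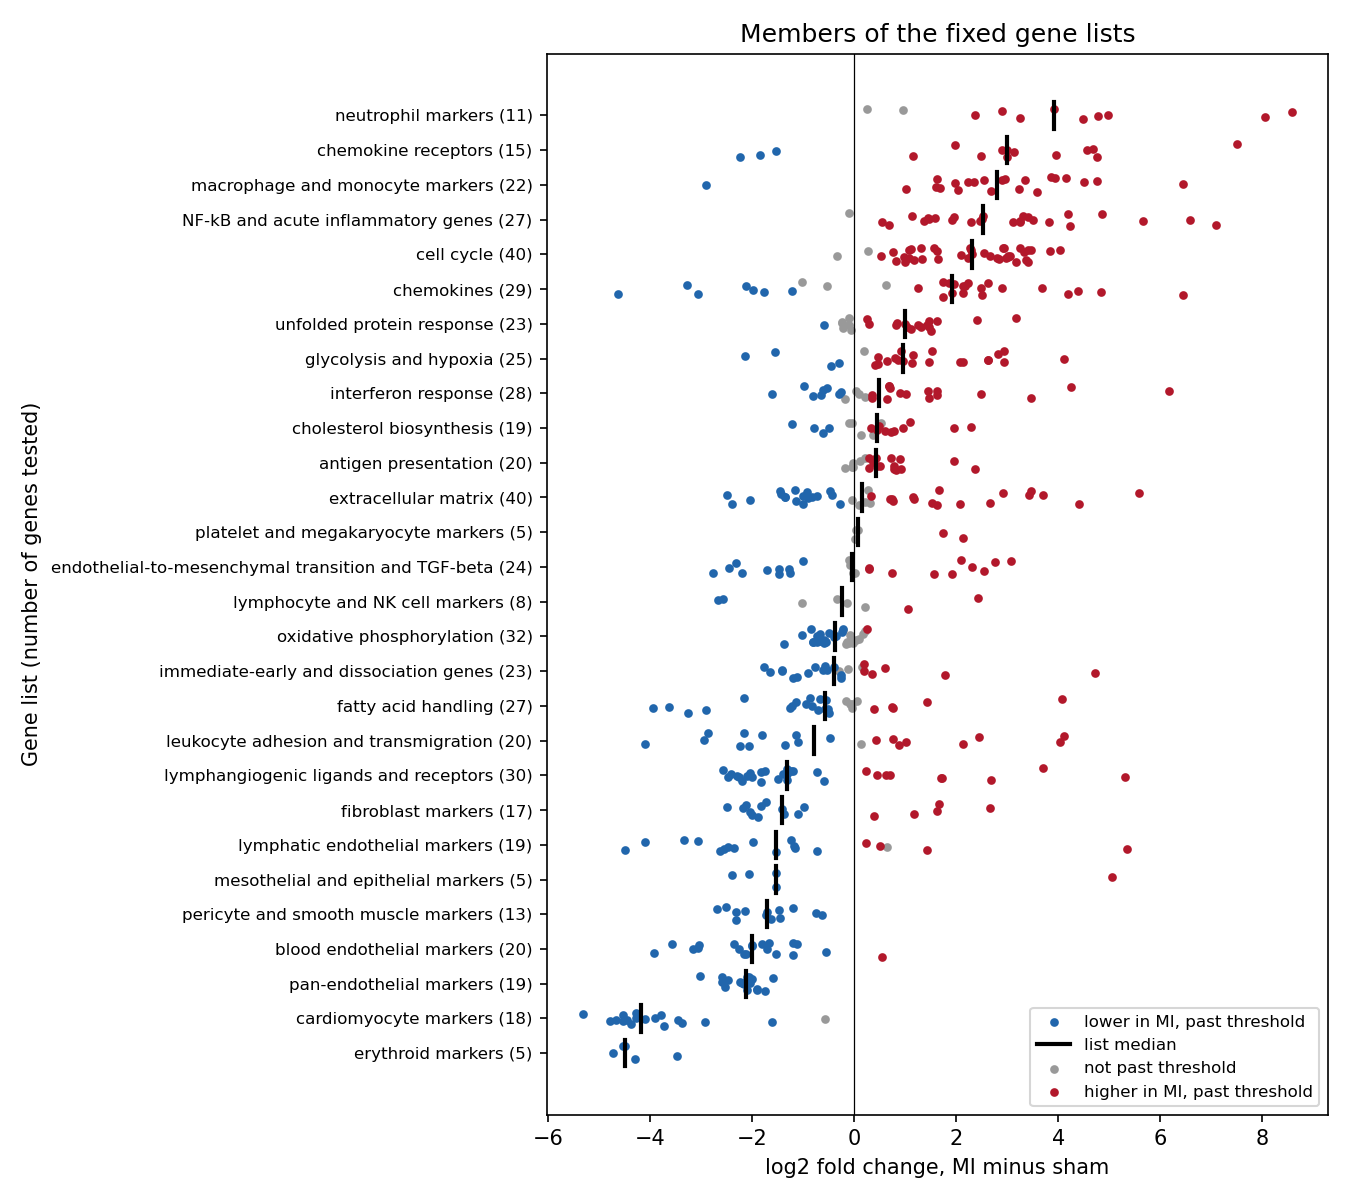
Each point is the log2 fold change (MI minus sham) of one tested gene, by gene list, with the number of genes tested in brackets; red and blue points passed the threshold, grey points did not, and a black bar marks the list median. Medians run from -4.49 for erythroid markers to 3.92 for neutrophil markers, and the extracellular matrix and platelet medians turn negative when libraries are scaled to total counts.

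Of the 30 lists, 28 had enough tested genes for camera and 19 passed it, 9 higher and 10 lower in MI; 10 passed with an estimated correlation. Several lists shared members, so their counts are not independent of one another.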

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

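The alternatives named as added in the methods were chosen after seeing the data, the others before. The count of genes past the threshold lay between 8596 and 10177 in every alternative but one: 4160 genes passed when a minimum fold change of 2 was tested, a stricter question by construction. Leaving out 1 library gave 8596 (without MI 3) to 9925 (without MI 1) genes, and thinning the MI libraries to the sham depth gave 8624, of which 8393 were among the 9801. DESeq2 gave 9373, RLE scaling 9831, limma-voom 9636 and log2(TPM + 1) 9361. The median over all genes, -0.01 in the main analysis, moved to -0.36 with total-count scaling, to -0.14 in TPM and to 0.12 without a filter. Ccl2 kept its direction and call in all 15 alternatives, at 1.61 to 2.02 log2. Of 1878 alternative values for 127 named genes, 1866 kept direction and call, 2 became weaker (both Cd79b, without sham 2 and with total-count scaling), 3 became stronger and 7 turned. Those that turned were near 0 and not called: Gp1ba went to -0.0068 with the stricter filter and -0.31 with total-count scaling, Itga2b to -0.27 with total-count scaling and -0.016 in TPM. With single libraries left out, Gp1ba ranged from -0.18 (without sham 3) to 0.42 and Itga2b from -0.17 (without sham 2) to 0.41; the cause was not tested.

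Same-numbered sham and MI libraries did not deviate together (correlations -0.048, -0.021 and 0.016), so no pairing by number was seen; with the replicate number as a block 9635 genes passed, 4764 higher and 4871 lower, and Ccl2 stayed at 1.96. Of 28 lists, 19 passed camera and 18 to 21 did under other scalings, filters, the block and left-out libraries. With an estimated correlation 10 passed. A correlation above the preset 0.01 does not account for every change. The estimate was 0.0024 for fatty acid handling genes, whose camera adjusted p went from 0.0212 to 0.118. For NF-kB and acute inflammatory genes it was -0.00038, with camera adjusted p of 2.23e-20 and 0.0124. The other lists that lost the call had estimates above 0.01. What else differed between the 2 settings was not tested. The lymphocyte list, not called in either case, had its camera direction turned with total-count scaling (median -0.59); the cause was not tested. Of all 406 list values under alternatives, 371 kept direction and call. The sham depth limits what can be seen of rare transcripts: 3 counts over the sham group are 0.26 CPM.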

Other observations

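The tests of depth and of other splits of the samples were set out before their results were seen; every other test below was chosen afterwards, as was the restriction of the tests on macrophage genes to part of their lists. The lists in this part were written after the main results were seen, and the genes named from them were chosen after their values were seen.

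Lysosomal genes were higher in MI across the list, with 31 of 32 tested past the threshold of edgeR's quasi-likelihood test and higher and 1 lower (median log2 fold change 2.42). The protease gene Ctsb went from 1208 ± 29.1 to 15155 ± 620.0 CPM (mean ± SD, n = 3), Ctss, a protease of antigen-presenting cells, from 334 ± 10.95 to 4280 ± 130.3 CPM, and Grn, the gene of the lysosomal protein progranulin, from 249 ± 9.03 to 2489 ± 284 CPM. The exception was Ctsf, which fell (log2 fold change -1.76 ± 0.14, SE). Of the 27 members whose values had not been looked at, 26 rose and 1 fell (limma camera adjusted p = 2.43e-21, and 0.00925 with an estimated correlation). The macrophage and monocyte list had a median of 2.79 in these libraries, with 21 of 22 members higher.

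Iron and heme handling genes rose at 15 of 19 and fell at 1, the plasma ferroxidase gene Cp. Fth1, the ferritin heavy chain gene, went from 1022 ± 32.6 to 9272 ± 1422 CPM, and Slc11a1, a phagosomal metal transporter, from 47.0 ± 4.03 to 453 ± 30.4 CPM; over the 16 members not looked at before, camera gave an adjusted p of 0.00198, and 0.0294 with an estimated correlation. Lipid uptake and cholesterol efflux genes divided into 12 higher and 5 lower of 18: the scavenger receptor gene Msr1, the cholesterol-esterifying enzyme gene Soat1 and the efflux pump gene Abca1 rose by 3.04 ± 0.12, 3.41 ± 0.12 and 2.81 ± 0.17 log2 (SE), while Cd36, Scarb1 and Vldlr fell by 2.16 ± 0.11, 0.91 ± 0.10 and 3.13 ± 0.28. Over its 13 members not looked at before, camera gave an adjusted p of 0.000475, and 0.0284 with an estimated correlation. Both lists moved beside the macrophage median of 2.79.

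Macrophage markers were higher and pan-endothelial markers lower in MI, with medians 4.91 log2 units apart. With the MI libraries thinned to the sham depth the gap was 4.88. Thinning lowers all genes alike and the libraries are then rescaled, so it bears on counting noise alone. It cannot decide on other differences that came with depth. A lower share of endothelial cells alone is argued against. It would raise the markers of every other cell type, and the cardiomyocyte median was -4.19 (SD 1.16 over genes). A change within endothelial cells alone was not tested for leukocyte genes. Their rise against endothelial genes restates the pattern, and no value here assigns their transcripts to a cell. Per 100 Pecam1 CPM, the pan-leukocyte gene Ptprc stood at 6.61 ± 0.256 in sham and 178 ± 31.7 in MI. The neutrophil list had a median of 3.92, with 9 of 11 genes higher and none lower. Other cells were present in sham too, where all 18 cardiomyocyte genes tested each averaged 1 CPM or more. More myeloid cells in the MI libraries cannot be told apart from a change within myeloid cells: 21 of 22 macrophage genes rose, which restates the pattern. Of the 22, 21 were also at 1 CPM or more in sham and 3 are in other lists. The labels name no sort or gate that would remove such cells. By their markers, neither group held lymphatic endothelial cells alone. Per 100 Pecam1 CPM, sham held 0.444 ± 0.0296 CPM of Prox1 and 447 ± 14.7 of Fabp4, from the blood endothelial list. Lyz2 stood at 119 ± 4.51 in sham and 2333 ± 117 in MI on the same scale. The operation, a difference in purity between the groups and an unstated library batch stay open and untested, since each follows the group.

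Ccl2 was higher in MI by 1.96 log2. At equal depth the value was 1.94. Thinning followed by rescaling hardly moves the fold change of a well-counted gene, so that value cannot decide on depth. More myeloid cells that carry Ccl2 stay possible. Ccl2 rose by 0.83 less than the macrophage median (-0.83, within the SD of 1.79 over that list). That SD is a wide spread across genes and the rule was chosen afterwards, so the test cannot decide. Relative to the mean of the macrophage list, Ccl2 went from 0.35 ± 0.10 in sham to -0.40 ± 0.03 in MI. Higher Ccl2 per endothelial cell cannot be told apart from more myeloid cells. Ccl2 rose 4.08 above the pan-endothelial median, which both explanations predict, and no value here assigns the transcripts to a cell. The operation itself and any library batch stay untested.

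Macrophage genes themselves moved apart. Of 12 genes typical of resident heart macrophages all 12 fell (median -3.08), among them Timd4 (36.3 ± 0.416 to 2.35 ± 0.389 CPM) and Vsig4, while of 12 genes linked to macrophages of injured tissue 11 rose (median 5.81), among them Spp1 (22.9 ± 7.39 to 7959 ± 185 CPM) and Gpnmb, and Cd9 fell; each list shares 1 gene with the macrophage list. Some of these values had been looked at when the lists were written and others belong to the fixed lists, whose results were known, so the tests used the remaining 9 resident-type and 3 injury-linked genes. The gap between these medians was 6.05 in the main analysis and 6.05 at equal depth. Thinning followed by rescaling hardly moves such a gap, so it cannot decide on depth. The injury-linked median was the value of Plin2 alone (3.76), and Cd9, also among the 3 genes, fell (SD 3.21 over genes). More of one unchanged kind of macrophage is argued against by the resident-type median of -2.29 (SD 2.67), against 2.79 for the macrophage list. That median was -2.90 over 11 genes before members of the fixed lists were left out. What moved these genes apart stays open, and the 3 injury-linked genes are few.

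The count of 9801 genes was set against the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 (the real one) gave as many genes, and the highest of the others gave 0 in edgeR's quasi-likelihood test, with 6 to 63 genes at an unadjusted p below 0.05 and 0 to 2 genes in DESeq2. With 10 splits the share cannot fall below 0.05, so the splits are too few for a test.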
